A study of Zea mays with 11 samples.

How the data were processed

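Bisulfite sequencing of genomic DNA was used to measure cytosine methylation in the maize inbred line Mo17. The 11 libraries are 2 whole-seed libraries, 8 libraries of dissected endosperm and 1 ear leaf library. Each stage has 1 library, so no stage has a replicate, and the p-values below measure the spread between libraries about a group mean or about a straight line in day.

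Reads were processed with cutadapt, Bismark and Bowtie2, per the submitters' processing notes, whose versions and settings are not given in the sources used here. The genome build and the width of the upstream region are also not given in the sources used here. The deposited tables hold 39656 gene models each and give, per the file headers, a count of methylated calls and a methylation level in percent for the CG, CHG and CHH contexts (H is A, C or T), in the gene body and in the upstream region. The count columns were deposited as whole numbers, and the percent columns, computed by the authors, are the methylated share of the calls. The total number of calls was recovered as the methylated count divided by the level, rounded to a whole number. Levels were deposited with 2 decimals, so each stands for a range of 0.005 percentage points to either side. For 800474 values above 0 this range spans under 0.1 call, so that few totals would be whole by chance, and a whole total lay within it for 100.0% of them. Where the methylated count was 0, the total was estimated from the other contexts of the same gene and library. A gene with 0 in all 3 contexts of a region can be uncovered or unmethylated, and was treated as missing there. The 57 chloroplast and 124 mitochondrial gene models were kept out of the gene tests. Those with a methylated count above 0 in a context were used as a check of bisulfite conversion. Leaving out those with a count of 0 raises these levels, the more so where calls are few.

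The libraries held 141135636 calls in the leaf to 218350456 in 11-day endosperm, counted where the methylated count was above 0. No pair of libraries held the same values. The median number of CG calls per gene body ran from 272 to 455, and from 233 to 355 in the upstream region. Wilson intervals at 95% are given for levels of single genes in the leaf, and cover counting error only, since reads without molecular identifiers are not independent molecules.

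Gene symbols came from an NCBI RefSeq table of assembly Zm-B73-NAM-5.0, used for names only. It matched 18775 of the 39475 nuclear gene models, of which 1128 had a gene symbol. Coordinates are those of the deposited files, whose build is not given in the sources used here. The 7 gene lists were fixed before the data were examined. Of the listed symbols, the table tied 19 gene models to starch synthesis, 21 to storage proteins and their regulators, 14 to the transfer layer and aleurone, 8 to Polycomb and imprinted genes, 9 to DNA methylation machinery, 12 to photosynthesis and 13 to housekeeping.

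Levels were tested with limma 3.58.1 in R 4.3.3, with 1 fit per context. The trend fit used the 8 endosperm libraries with day as a number, and its changes are given over the 18 days from 7 to 25. The tissue fits used all 11 libraries, with the leaf assumed to vary like the other tissues. In every fit, genes needed at least 10 calls in each of the 11 libraries and, for CG and CHG, a mean level of at least 1% over them. The threshold was a Benjamini-Hochberg adjusted p of 0.05. Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation. Mean levels per library were compared with day by exact permutation of the 40320 pairings, and between groups by exact permutation of all splits, all two-sided, in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1; figures were drawn with matplotlib 3.10.9.

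The gene body was the region chosen before the data were examined, together with the tests, lists, alternatives and the rule for named genes. The upstream region, the gene classes by leaf level and the whole-seed contrast without the 10-day library were chosen after seeing the data. The rule named, per contrast and context, up to 4 members of each list past the threshold by size of change, or the 2 with the largest change where none passed, and then the 5 largest increases and 5 largest decreases among genes past the threshold with a symbol, up to 30 genes per contrast, with the context with the most calls first. The same rule was used for the upstream region. The genes described are a part of those the rule named, picked after their values were seen.

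The fits were tested on simulated data with 200 changed genes per comparison, in both regions. Changed genes were drawn from a limited range of mean levels. The simulated spread was the observed one, which already holds counting error, with counting error added again. The shares called depend on these settings and on the number of changed genes, and are not the detection rates of the real fits. In the gene body, for whole seed against endosperm, 59.0% of the genes changed by 40 percentage points in CHG were called and 11.9% of those changed by 20, with 2 unchanged genes among 55 calls over 31142 genes. For seed in CHH, 16 of 92 calls over 32485 genes were unchanged genes, and in CG 5 of 48 over 30228. For the leaf, unchanged genes made up 5 of 26 calls over 30228 genes in CG, 9 of 34 over 31143 in CHG and 53 of 111 over 32486 in CHH, so the adjusted p understates false calls for the leaf. Their share was also above 0.05 in some seed and trend fits, such as seed in body CHH, body CG and upstream CHG and the upstream CHH trend. Those calls can also hold more false ones than the threshold states. For the endosperm trend in CHG, 12.8% of the genes changed by 40 percentage points were called over 31137 genes, and for CG 3.08% over 30228 genes. In the upstream region, 37.5% of the genes changed by 40 percentage points in CHG were called for seed over 36075 genes, 8.93% for the leaf and 0 for the trend, with unchanged genes in 4 of 35 seed calls and 1 of 6 leaf calls. In upstream CHH 2 of 18 trend calls, 0 of 39 seed calls and 16 of 52 leaf calls were unchanged genes, and 19.4%, 45.0% and 39.4% of the genes changed by 10 percentage points were called. In upstream CG 0 of 2 trend, 0 of 30 seed and 0 of 3 leaf calls were unchanged genes.

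Alternatives were the arcsine square root scale, no filter on low levels, coverage minimums of 5 and 20, subtraction of each library median, moderation with a trend and robust fitting, a quasi-binomial model on calls, a minimum change of 10 percentage points (2 for CHH), other time axes, day as a covariate, and leaving out libraries.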

Results

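The series follows DNA methylation through maize seed development, from 2 whole-seed libraries (3 and 5 days after pollination) through 8 libraries of dissected endosperm taken between day 7 and day 25, with an ear leaf of 13 days as the control tissue. Its title names starch synthesis as the process of interest. The plants were field grown and self-pollinated. The tables held 141135636 cytosine calls for the leaf, 152120262 for 3-day seed, 192707018 for 5-day seed and from 149059601 (day 13) to 218350456 (day 11) for endosperm.

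Mean CHG levels and the gene body CHH level were lower in endosperm than in whole seed, and the leaf had values above those of endosperm. The mean gene body CHG level was 19.5% ± 1.39 (SD, n = 8) in endosperm, 23.5% ± 0.613 (SD, n = 2) in whole seed and 23.5% in leaf. Upstream of genes the CHG level was 46.6% ± 3.15 (SD, n = 8) in endosperm, 55.3% ± 0.992 (SD, n = 2) in whole seed and 56.2% in leaf. The body CHH level was 1.66% ± 0.115 (SD, n = 8) in endosperm, 2.43% ± 0.180 (SD, n = 2) in whole seed and 2.05% in leaf. The difference of whole seed from endosperm was the largest of the 45 splits of these libraries in body CHG, body CHH and upstream CHG (exact permutation p = 0.022 each, adjusted over 6 comparisons p = 0.044). In upstream CHH it was 1.38 percentage points (exact permutation p = 0.044, adjusted p = 0.067). Body CG, at 32.5% against 30.8%, gave an exact permutation p of 0.067 and upstream CG, at 62.4% against 60.3%, one of 0.20. The leaf lay above all 8 endosperm libraries in 5 of the 6 measures and above 7 in upstream CHH. With 1 leaf library the smallest p that the splits allow is 0.111, so this difference has no test at the threshold.

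**Figure D1:**
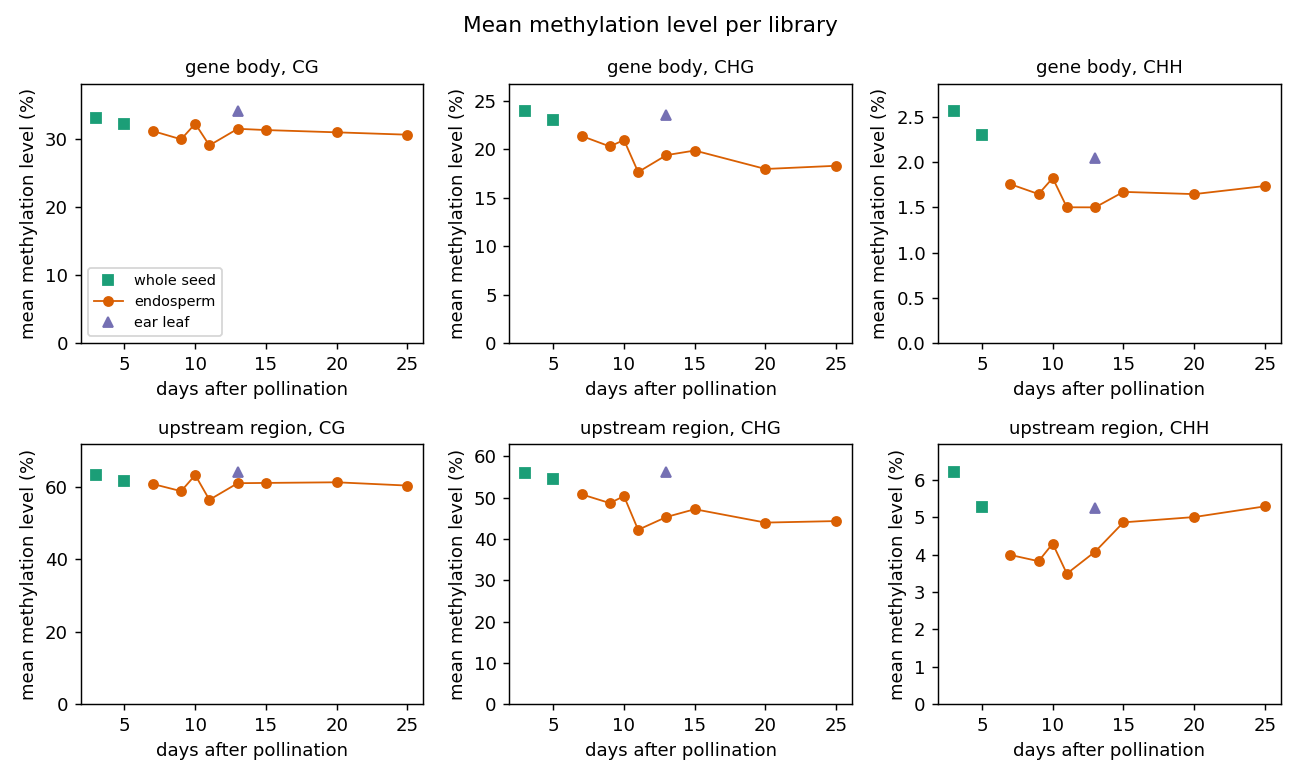
Mean methylation level over genes (%) per library against days after pollination, for the gene body (top) and the upstream region (bottom) in CG, CHG and CHH. Each point is 1 library (squares whole seed, circles endosperm, triangle ear leaf), with no error bar because each stage has 1 library, and upstream CHG is 50.8% at day 7 and 44.3% at day 25, below both seed libraries and the leaf.

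The endosperm series asks how methylation of genes changes as the tissue fills. Upstream CHH methylation rose: the mean over genes was 3.99% at day 7, 3.49% at day 11 and 5.29% at day 25, a fitted change of 1.61 percentage points over 18 days (Pearson r = 0.857, exact permutation p = 0.0048, adjusted over 6 relations p = 0.029). Spearman's rho was 0.786 (exact permutation p = 0.028, adjusted p = 0.139). The median over genes gave r = 0.645 (exact permutation, adjusted p = 0.149). For the mean over genes, r was 0.571 without the 20- and 25-day libraries (exact permutation p = 0.219). With 1 stage left out, the adjusted p was 0.254 without day 25, 0.102 without day 20, 0.0964 without day 9 or day 15 and 0.0690 without day 13, and it stayed under the threshold without day 7, 10 or 11. Upstream CHG was 50.8% at day 7, 42.2% at day 11 and 44.3% at day 25 (r = -0.603, exact permutation p = 0.116, adjusted p = 0.232; rho = -0.690, exact permutation p = 0.069, adjusted p = 0.139; r = -0.517 without days 20 and 25). Body CHG gave r = -0.664 (exact permutation p = 0.073, adjusted p = 0.220; rho = -0.690, exact permutation p = 0.069; r = -0.468 without days 20 and 25). Neither CHG relation passed, except without the 11-day library, where r was -0.912 in the body (exact permutation, adjusted p = 0.0155) and -0.869 upstream (exact permutation, adjusted p = 0.0230). Body CG, body CHH and upstream CG gave r of 0.005, 0.028 and 0.122 and rho of -0.048, -0.262 and 0.190, with exact permutation p of at least 0.536 (r of 0.138, -0.430 and 0.0759 without days 20 and 25).

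Genes were also grouped by the CHH level of their upstream region in leaf, a grouping chosen after seeing the data, and upstream CHH rose with day in the 2 classes with the higher leaf levels. In the 4753 genes with at least 10% upstream CHH in leaf, the mean was 8.87% at 7 days and 12.8% at 25 days of endosperm (r = 0.882, exact permutation p = 0.002, adjusted over 18 relations p = 0.022; rho = 0.762, exact permutation p = 0.037, adjusted p = 0.156). In the 7742 genes at 5 to 10% it was 4.84% and 6.82% (r = 0.893, exact permutation p = 0.002, adjusted p = 0.022; rho = 0.833, exact permutation p = 0.015, adjusted p = 0.131). In the 23094 genes under 5% it was 2.65% and 3.18% (r = 0.629, exact permutation p = 0.099, adjusted p = 0.289; rho = 0.524, exact permutation p = 0.197). Without days 20 and 25, r was 0.696, 0.654 and 0.196. Whether the classes differ in slope was not tested.

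**Figure D2:**
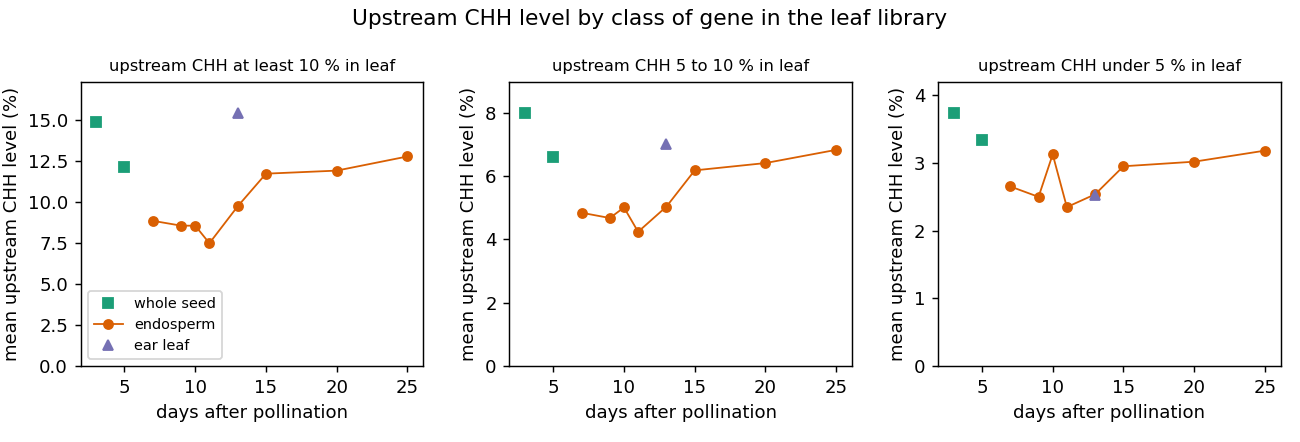
Mean upstream CHH methylation level (%) per library against days after pollination, for 3 classes of genes by their level in the leaf library. Each point is 1 library (squares whole seed, circles endosperm, triangle ear leaf, which defines the classes), and in the class of at least 10% the endosperm is at 8.87% on day 7 and 12.8% on day 25.

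At single genes, 693 of 37481 upstream regions changed in CHH with day (limma, adjusted p under the threshold), 691 of them upwards. They included act1, an actin gene (GRMZM2G126010, +6.89 percentage points over 18 days, SE 0.841, adjusted p = 0.0204), and nrp1 (GRMZM2G062650, +11.9, SE 1.68, adjusted p = 0.0255). They also included met2 of the DNA methylation machinery list (GRMZM2G025592, +9.00, SE 1.40, adjusted p = 0.0292) and the alpha-zein gene z1A1_2 (GRMZM2G404459, +18.6, SE 2.31, adjusted p = 0.0204), a member of a family of near-identical copies between which reads can be shared. COAC2 (GRMZM2G161299) rose by 25.1 percentage points (SE 4.52, adjusted p = 0.0423) and pdi7 (GRMZM2G159369), a protein disulfide isomerase gene, by 18.9 (SE 3.53, adjusted p = 0.0460). Of the 18 measured starch synthesis genes, 16 had an upstream CHH change above 0 and the median was +2.15 percentage points. The median over all genes was +0.580. Every other list also had a median above 0: storage proteins and regulators +2.68, Polycomb and imprinted genes +2.10, housekeeping +1.95 (10 of 13 above 0), photosynthesis +1.69 (8 of 11), DNA methylation machinery +1.44 (8 of 9) and transfer layer and aleurone +0.740 (9 of 14). A rise was thus not particular to the starch list. None passed over all genes and 6 passed adjusted over the list alone. The list gave an adjusted camera p of 0.0244 with the preset correlation and an adjusted p of 0.449 with an estimated correlation. Among them were du1, a starch synthase gene, at +8.65 (SE 2.28, adjusted p = 0.110), and ae1, a starch branching enzyme gene, at +8.23 (SE 2.14, adjusted p = 0.105). Of the 20 storage protein genes and regulators 13 were above 0, 0 passed over all genes and 5 passed adjusted over the list alone (limma). The other 5 lists gave 1 gene each for Polycomb and imprinted genes (nrp1), DNA methylation machinery (met2, with 2 genes adjusted over the list alone) and housekeeping (act1), and 0 for the transfer layer and aleurone and for photosynthesis. The count of 693 fell to 0 without the 25-day library, to 70 without the 10-day library, to 141 without the 9-day, 206 without the 11-day, 329 without the 7-day and 443 without the 20-day library. It was 0 with trended and robust moderation and 33 on the arcsine scale.

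In the gene body, 9 of 32488 genes rose in CHH, among them nfd102 (GRMZM2G145968) by 6.13 percentage points (SE 0.599, adjusted p = 0.0397). That count was 6 or lower when any 1 endosperm library was left out, and 0 without the 7-, 10- or 25-day library. Body CG and CHG gave 0 genes by limma, with 1630 and 2363 genes at an unadjusted p under 0.05, and 0 by the quasi-binomial model. Upstream CG and CHG also gave 0 by both, with 2017 and 4059 genes at an unadjusted p under 0.05. The gamma-zein gene gz50 (GRMZM2G138689) had a body CHG change of -42.1 percentage points (SE 10.3, adjusted p = 0.480). In body CHG, 10 of 12 transfer layer and aleurone genes and 15 of 19 starch synthesis genes were below 0, with adjusted camera p of 0.0727 and 0.560 and with 1 and 0 genes passing adjusted over the list alone. Upstream CHG was above 0 in 7 of 9 DNA methylation machinery genes, with an adjusted camera p of 0.0238 with the preset correlation and an adjusted p of 0.428 with an estimated correlation.

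Whole seed was compared with endosperm to see which genes are less methylated in the dissected tissue. The seeds were younger than every endosperm sample, so tissue and age change together. Several genes known for expression in endosperm were more methylated in whole seed. The body of fie1, an imprinted Polycomb gene expressed in endosperm (GRMZM2G118205, chromosome 4, 35757180 to 35763186), had a CG level of 80.7% ± 4.96 (SD, n = 2) in seed and 30.7% ± 10.6 (SD, n = 8) in endosperm (limma adjusted p = 0.0220), and CHG levels of 56.8% and 19.9% (adjusted p = 0.0124). The alpha-zein gene fl2 (GRMZM2G397687, chromosome 4, 21312310 to 21313379) had CHG levels of 90.6% ± 3.87 (SD, n = 2) and 52.5% ± 5.37 (SD, n = 8) (limma adjusted p = 0.00499). The zein regulator pbf1 (GRMZM2G146283, chromosome 2, 153510052 to 153513609) had CHG levels of 83.3% ± 1.61 (SD, n = 2) and 42.7% ± 9.23 (SD, n = 8) (limma adjusted p = 0.0167).

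**Figure D3:**
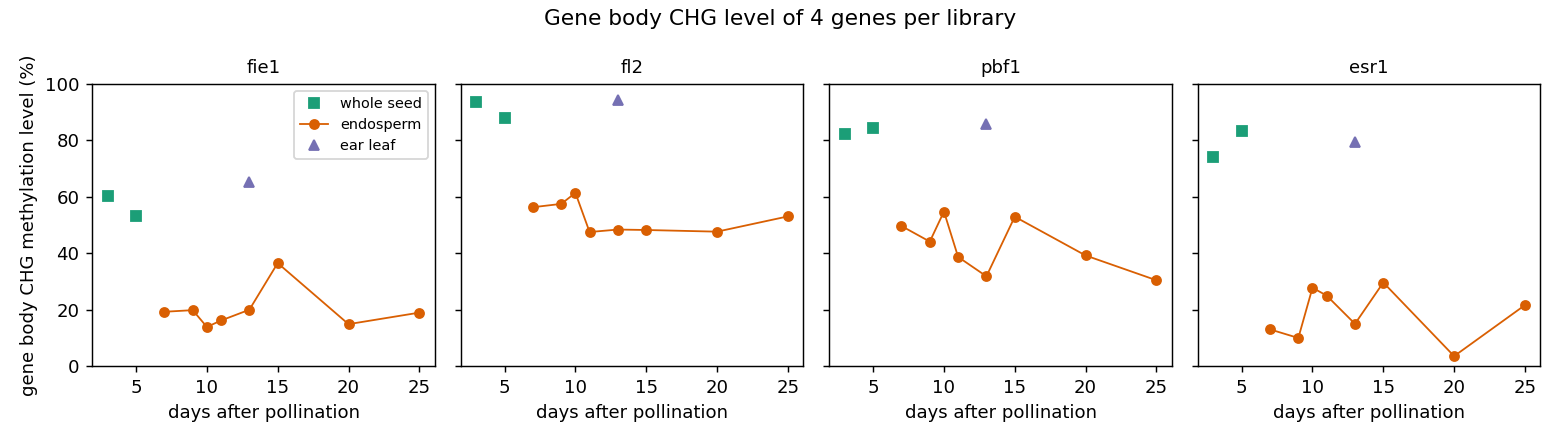
Gene body CHG methylation level (%) of fie1, fl2, pbf1 and esr1 per library against days after pollination. Each point is 1 library (squares whole seed, circles endosperm, triangle ear leaf), and mean levels in whole seed are 56.8%, 90.6%, 83.3% and 78.8% against 19.9%, 52.5%, 42.7% and 18.2% in endosperm.

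By list, 4 of 12 transfer layer and aleurone genes were higher in seed in body CHG (6 adjusted over the list alone), with a median of +27.3 percentage points. They were esr1 of the embryo-surrounding region (GRMZM2G046086, 78.8% against 18.2%, adjusted p = 0.00571, on as few as 10 calls in a library), ebe2 (GRMZM2G167733, 84.4% against 46.7%, adjusted p = 0.0438), meg2 (GRMZM2G088896, 95.4% against 64.0%, adjusted p = 0.0410) and ebe1 (GRMZM2G129157, 74.0% against 44.9%, adjusted p = 0.0371), all genes of the basal or embryo-surrounding endosperm. All 19 storage protein genes and regulators were above 0 and 3 passed (5 adjusted over the list alone): fl2, pbf1 and the alpha-zein gene az22z3 (GRMZM2G044625, 87.3% against 42.7%, adjusted p = 0.0346). Zein, esr and meg genes have near-identical copies between which reads can be shared, so their values are uncertain. The adjusted camera p was 0.00168 for the transfer layer list and 0.00572 for the storage protein list with the preset correlation, and an adjusted p of 0.281 for both with an estimated correlation. In body CG the same lists gave adjusted camera p of 0.0135 and 0.0463, and 0.355 and 0.388 as adjusted p with an estimated correlation. Of 19 starch synthesis genes 2 passed in body CHG (2 adjusted over the list alone): sh2, which encodes a subunit of ADP-glucose pyrophosphorylase (GRMZM2G429899, 36.0% against 17.3%, adjusted p = 0.0167), and the branching enzyme gene sbe1 (GRMZM2G088753, +26.8 percentage points, SE 5.27, adjusted p = 0.0320), a symbol that 2 gene models carry. The other sbe1 model (GRMZM2G088737) was among the 19 measured and did not pass. The symbols pbf1 and meg2 are also carried by 2 gene models each. The other pbf1 model (GRMZM2G146267) had a body CHG change of +2.92 (SE 2.71, adjusted p = 0.656), and the other meg2 model was not measured there. In body CHG, 1 of 8 Polycomb and imprinted genes passed (fie1, with 3 genes adjusted over the list alone), 1 of 10 photosynthesis genes (rca1), and 0 of 9 DNA methylation machinery genes and 0 of 13 housekeeping genes.

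Over all genes, 1307 of 31143 gene bodies differed in CHG (1294 higher in seed), 1762 of 32488 in CHH (1761 higher) and 375 of 30228 in CG (358 higher). In CHH, prcw1 (GRMZM2G049915) was at 33.7% ± 0.665 (SD, n = 2) in seed and 3.84% ± 2.12 (SD, n = 8) in endosperm (limma adjusted p = 8.9e-06). In the same context adh1, an alcohol dehydrogenase gene (GRMZM2G442658), was at 12.6% and 2.25% (adjusted p = 0.000598). rca1, rubisco activase (GRMZM2G162200), was at 5.75% and 0.823% (adjusted p = 7.5e-05) and the transfer layer gene betl2 (GRMZM2G152655) at 7.93% and 2.58% (adjusted p = 0.0125). Upstream, 5291 of 36075 genes differed in CHG (5282 higher in seed), including the zein regulator o2 (GRMZM2G015534, 73.7% against 45.0%, adjusted p = 0.0260) and esr3 (GRMZM2G140302, 85.9% against 33.5%, adjusted p = 0.00630). Others were the Polycomb gene fie2 (GRMZM2G148924, 78.7% against 32.7%, adjusted p = 0.0190) and the methyl-CpG-binding domain gene mbd111 (GRMZM2G025095, 84.5% against 36.0%, adjusted p = 0.0151). Of 18 starch synthesis genes 16 were above 0 in upstream CHG and 4 passed (9 adjusted over the list alone), with an adjusted camera p of 0.172. They were the branching enzyme genes sbe3 (GRMZM2G005298, 78.6% against 59.0%, adjusted p = 0.0354) and ae1 (GRMZM2G032628, 65.6% against 51.3%, adjusted p = 0.0280), the sucrose synthase gene sus1 (GRMZM2G152908, 62.9% against 48.7%, adjusted p = 0.0375) and the debranching enzyme gene zpu1 (GRMZM2G158043, 86.7% against 73.2%, adjusted p = 0.0217). Other lists were also above 0 in upstream CHG. There 13 of 14 transfer layer and aleurone genes were above 0 and 5 passed (esr3, esr2, betl3, ebe2 and esr1, the last named after its values were seen), with an adjusted camera p of 0.0891. Of 19 storage protein genes and regulators 17 were above 0 and 2 passed (o2 and pbf1). Of 12 housekeeping genes 10 were above 0 and 1 passed (tub2, with 4 adjusted over the list alone). For the remaining lists the counts were, of 8 Polycomb and imprinted genes 6 and 1 (fie2), of 9 DNA methylation machinery genes 6 and 0, and of 11 photosynthesis genes 9 and 0. Upstream CHH differed at 2825 genes (2815 higher), with o7 (GRMZM2G074759) at 9.08% and 1.85% (adjusted p = 0.00107), and upstream CG at 187.

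With day as a covariate, as a straight line that extends to the younger seeds, the count was 7 in body CHG (median change per gene 0.499 percentage points, median SE 1.81, against 0.739 and 1.46 without the covariate). In upstream CHG it was 0 (limma, 5822 genes at an unadjusted p under 0.05; median change 5.50, median SE 5.71, against 8.67 and 4.83), so smaller changes and larger SEs came together. In CHH it was 776 in the body (median change 0.249 against 0.301) and 2712 upstream (median change 1.27 against 0.740). For CG the count was 31 in the body (median change 0.429 against 0.331, median SE 3.53 against 2.88) and 0 upstream (limma, 3117 genes at an unadjusted p under 0.05). Against the 7- and 9-day endosperm alone, with 4 libraries, limma gave 0 in each context and region, with 2957 to 5945 genes at an unadjusted p under 0.05. The median changes were then 0.620 in body CHG, 5.00 in upstream CHG, 0.305 in body CHH and 1.06 in upstream CHH. Subtracting library medians takes 11.6 percentage points more from seed than from endosperm in upstream CHG, above the median change of 8.67. A fall of the count there follows from that construction and does not show a shift shared by all genes. After that subtraction the count there was 76 (54 higher and 22 lower in seed). Without the 3-day seed it was 84 in body CHG, 74 in body CG, 1118 in body CHH and 0 in upstream CHG, with 951 in upstream CHH and 2 in upstream CG. Without the 5-day seed it was 319 in body CHG, 195 in body CG, 2621 in body CHH and 33 in both upstream CHG and upstream CG.

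The leaf shows methylation of the same genes in a tissue outside the seed. It is 1 library, so its difference from endosperm has no replicate check, and its values describe this library. The genes below were named by the size of their leaf difference in these same values, and those lower in leaf are not described. That the leaf lay above the mean of the 8 endosperm libraries at each of them therefore follows from the choice. fie1 had a body CG level of 84.1% in leaf (95% Wilson interval 80.4 to 87.2%, 452 calls) against 30.7% ± 10.6 (SD, n = 8) in endosperm, and a CHG level of 65.2% (61.1 to 69.1%) against 19.9% ± 7.09 (SD, n = 8). In fl2 the leaf CHG level was 94.2% (91.0 to 96.3%) against 52.5% ± 5.37 (SD, n = 8), and in pbf1 the CG level was 97.0% (92.5 to 98.8%) against 49.1% ± 10.3 (SD, n = 8). The histone deacetylase gene hda110 (GRMZM2G107309) had CG levels of 74.5% (71.6 to 77.2%) and 35.1% ± 5.85 (SD, n = 8). In ftr1 (GRMZM2G122793) the CG level was 71.2% (64.4 to 77.2%) in leaf, 22.8% ± 6.50 (SD, n = 8) in endosperm and 21.6% in whole seed. The body CHG level of esr1 was 79.3% (61.6 to 90.2%, 29 calls) in leaf and 18.2% ± 9.25 (SD, n = 8) in endosperm. In body CHH, prcw1 was at 15.1% (12.4 to 18.2%) and 3.84% ± 2.12 (SD, n = 8). The kinase gene ltk2 (GRMZM2G330907) was at 8.21% (7.56 to 8.91%) and 3.29% ± 0.665 (SD, n = 8). The lipoxygenase gene lox3 (GRMZM2G109130) was at 16.8% (15.2 to 18.5%) and 7.85% ± 1.86 (SD, n = 8). In upstream CHG, esr3 was at 91.0% (84.9 to 94.8%) and 33.5% ± 5.72 (SD, n = 8) and esr2 (GRMZM2G315601) at 91.8% (89.4 to 93.7%) and 69.6% ± 4.74 (SD, n = 8). The zein gene z1C1_7 (GRMZM2G346897) was at 88.5% (85.6 to 90.8%) and 47.1% ± 7.79 (SD, n = 8), and o2 at 79.4% (72.3 to 85.0%) and 45.0% ± 9.35 (SD, n = 8).

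By list, the median difference of the leaf from the endosperm mean in body CHG was +21.7 percentage points in the transfer layer and aleurone list (9 of 12 genes above 0), and +1.52 in Polycomb and imprinted genes. It was +0.871 in storage protein genes and regulators, +0.234 in DNA methylation machinery, -0.0125 in starch synthesis, -0.446 in housekeeping and -0.633 in photosynthesis. In upstream CHG all 14 transfer layer and aleurone genes were above 0 (median +11.6), as were 17 of 18 starch synthesis genes (median +8.69), beside a median of +9.96 over all genes. The median was larger in housekeeping genes, at +14.6 (10 of 12 above 0). It was +9.54 in Polycomb and imprinted genes, +6.13 in storage proteins and regulators, +5.89 in DNA methylation machinery and +4.66 in photosynthesis. Against 13-day endosperm alone, upstream CHG was higher in leaf at 28955 genes and lower at 7054, with a median difference of 10.9 percentage points.

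A limma fit in which the leaf is assumed to vary like the other tissues put 496 genes past the threshold in body CG (482 higher in leaf), 262 in body CHG (258 higher), 599 in body CHH (599 higher), 1011 in upstream CHG (991 higher), 806 in upstream CHH and 63 in upstream CG. These counts tell how far this library lies from endosperm and do not show a difference between tissues: the 10-day endosperm library set against the rest in the same fit gave 556 genes in body CG and 371 in body CHH. In simulated data 53 of 111 leaf calls in body CHH were unchanged genes. Upstream CHG gave 3642 genes without the 7-day library and 66 to 677 without each of the others, and body CHG 833 without the 7-day library and 140 to 146 without the 13-, 15-, 20- or 25-day library. In upstream CG the count was 20, 28 and 34 without the 9-, 11- and 15-day library. The quasi-binomial model gave 71 in body CG and the arcsine scale 294.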

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

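The tests of coverage, conversion, tissue share and age below were chosen only after the results were seen. The counts over other groupings of the libraries were planned before, except that the upstream region was added after seeing the data. Among 69 sets of 8 endosperm values, chance alone puts a library apart in about 1 of 20.

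The 10-day endosperm library stood far from the other endosperm libraries in coverage. It had methylated calls at 539 gene models without a methylated call in at least 9 of the other libraries, against 33 to 78 in the other endosperm libraries. Such gene models can be uncovered or unmethylated in those libraries. Its median relative coverage of low-coverage gene models was 0.184 against 0.0103 to 0.0196. Its mean correlation with the other endosperm libraries across genes was also lowest, at 0.956 against 0.962 to 0.967 in body CG and 0.900 against 0.921 to 0.929 in upstream CG. Depth is argued against, since the deeper 11-day library had methylated calls at 78 such gene models. So is more even coverage of the same DNA, since coverage at low-coverage gene models was 3.72 times the value extrapolated from well-covered ones. DNA from a genotype closer to the reference may have been mixed in, which stays open. Relative coverage had an intercept of 0.213 on that of the other libraries, above every other library (0.121 in the 11-day library). Flatter coverage also gives a positive intercept, so the intercept alone cannot tell mixed DNA from more even coverage. Other read processing stays open as untested, and no biological explanation was tested. The 10-day library had the highest endosperm CHH level in the low-methylation bodies defined in the next paragraph, at 1.32% against 0.84 to 1.06%. Their CG level was 2.74% against 1.88 to 2.23%. CHH was also highest in its mitochondrial (0.994%) and chloroplast (1.02%) gene models. Their CG levels (1.69% and 2.125%) lay within the range of the other endosperm libraries. Whether conversion was less complete in this library was not tested.

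The rise of upstream CHH methylation with day in endosperm is argued not to come from incomplete bisulfite conversion, because the CHH level of 10862 low-methylation bodies (under 5% CG and CHG in leaf) changed by -0.215 percentage points over 18 days (SE 0.157), against 1.61 upstream of genes. Mitochondrial and chloroplast gene models changed by -0.275 (SE 0.126) and -0.192 (SE 0.104). A rising share of other seed tissue stays open, since no profile of such tissue was measured at these days: upstream CHG, which is higher in whole seed, changed by -5.64 percentage points (SE 3.05). Whether the rise rests on the 20- and 25-day libraries alone stays open, with r = 0.571 over the other 6 stages, too few for that r to pass. A change with endosperm development stays among the open explanations, as untested. Chance in the order of days is argued against by the counts of genes but is not excluded. The real order gave 693 upstream and 9 body genes in CHH. Of 100 orders of the libraries, the real one included, 2 gave as many upstream and 1 in the body (highest other 5). The highest other upstream was 836, from an order that is close to the real one, with r = 0.988 between both. With 100 orders and 1 library per stage, these shares cannot exclude chance.

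The higher mean CHG and CHH levels of whole seed are argued not to come mainly from incomplete conversion, which acts on unmethylated cytosines and would raise low-methylation bodies as well. Those were 0.165 percentage points higher in seed in CHG (SE 0.0887) against 3.98 over all gene bodies, and 0.210 higher in CHH (SE 0.0569) against 0.770. Mitochondrial gene models were 0.359 higher in CHG (SE 0.0535) and 0.058 in CHH (SE 0.0515). Chloroplast gene models were 0.099 higher in CHH (SE 0.0743) but 5.11 higher in CHG (SE 1.11), a difference whose cause was not tested. Tissue and age of the seed cannot be told apart, because both seed libraries are younger than every endosperm library. With day as a covariate 7 genes passed in body CHG, 776 in body CHH, 0 in upstream CHG and 2712 in upstream CHH, against 1307, 1762, 5291 and 2825 without it, and a course with age other than a straight line was not tested. Chance in the choice of libraries is argued against but is not excluded, since 1 of 45 is the smallest share that the splits can give. Only the real split gave as many genes, with 375 in body CG (highest other 5), 1307 in body CHG (highest other 2) and 1762 in body CHH (highest other 33). Every other split left at least 1 seed library among the endosperm, which can widen the spread there and lower its count. For the leaf the 9 splits are too few for a share under 0.05. The leaf gave 496 genes in body CG and 599 in body CHH, 2 and 1 of the 9 splits gave as many, and the highest other was the 10-day library with 556 and 371.

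Other libraries stood apart in single values. The 11-day library had 127726661 body calls against 84287103 to 102181805 in the other endosperm libraries. The body CHG level of fie1 was 36.5% at day 15 against 13.9 to 20.0% at the other endosperm stages. The upstream CHG level of o2 was 25.0% at day 11 against 41.7 to 55.6%. Chloroplast gene models, used for the conversion check and left out of the gene tests, had a CG level of 6.60% in 3-day and 5.79% in 5-day whole seed, above the 2.26% of the leaf and the 1.97 to 2.85% of endosperm. Their CHG level was 8.59% and 6.38%, above 2.41% in leaf and 2.10 to 2.72% in endosperm. These CHG levels rest on few calls in seed: 9504 and 17095, against 29490 (day 13) to 78272 (day 11) in endosperm. The methylated calls in CHG, 816 and 1090 in seed, lay within the 649 (day 13) to 1640 (day 11) of endosperm.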

How the results depend on the processing

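The tests of the upstream region, of gene classes and of the whole-seed contrast without the 10-day library were chosen after seeing the data, and unless stated the cause of a change was not tested. Of 288 alternative counts, 194 stayed within 1.5 times the value reported, 91 moved further and 3 reversed. The 194 include counts of 0 that stayed 0, as in most alternatives of the CG and CHG trends, so results with calls moved more often than these numbers tell. Of 60 alternative correlations of mean level with day, 52 kept their side of the threshold. The 6 that no longer passed were all of upstream CHH, the only relation that had passed, and 2 of CHG newly passed. Of the relations that did not pass, those near 0 also changed sign: r ran from -0.484 to 0.186 in body CG, from -0.621 to 0.216 in body CHH and from -0.0402 to 0.338 in upstream CG. On the arcsine scale the counts were 294, 503 and 79 for the leaf in body CG, CHG and CHH, 794 for seed in body CHH and 0 for the body CHH trend. Upstream they were 115, 1757 and 46 for the leaf in CG, CHG and CHH, 284 and 1439 for seed in CG and CHH, and 33 for the CHH trend. Subtracting library medians takes 4.13 percentage points more from each leaf value than from endosperm in body CG, 4.51 in upstream CG and 12.5 in upstream CHG, above the median changes per gene of 0.974, 3.57 and 9.96. The reversals of the leaf there follow from that construction and say nothing on single genes: body CG gave 6196, of which 5473 lower, upstream CG 29, of which 15 lower, and upstream CHG 32, of which 22 lower. Seed then gave 186 and 1049 in body CG and CHH and 107, 76 and 1200 in upstream CG, CHG and CHH, and the body CHH trend gave 16. In upstream CHG, where 11.6 more was taken from seed against a median change of 8.67, the split for seed was 54 higher and 22 lower. The quasi-binomial model gave 71 and 218 for the leaf in body CG and CHH, 2163 for seed in body CHG and 68 for the body CHH trend. Upstream it gave 19, 2425 and 302 for the leaf in CG, CHG and CHH, 491 and 8040 for seed in CG and CHG, and 1364 for the CHH trend. With day as a covariate the seed gave 31, 7 and 776 in body CG, CHG and CHH and 0, 0 and 2712 in upstream CG, CHG and CHH. The leaf gave 566 in body CHG and 38 and 2048 in upstream CG and CHG. Against days 7 and 9 only, with fewer libraries, the seed gave 0 throughout. By rank of stage the trend gave 2 in body CHG, 1 in body CHH and 11 in upstream CHH. On log2 of day it gave 0 in body CHH and 114 in upstream CHH, and without days 20 and 25, with fewer libraries, 0 in both. Moderation with trend and robust fitting gave 0 for both CHH trends and 220 for the leaf in upstream CHG. With 1 library left out at a time, which also lowers the number of libraries, the ranges were 74 to 319, 84 to 1040 and 1118 to 2621 for seed in body CG, CHG and CHH, and 2 to 163, 0 to 5679 and 951 to 3402 upstream. For the leaf they were 140 to 833 in body CHG and 20 to 70 and 66 to 3642 in upstream CG and CHG. They were 0 to 1 for the body and upstream CHG trends, 0 to 6 for the body CHH trend and 0 to 768 for the upstream CHH trend. The lowest seed values came without the 3-day seed, and a lone seed is assumed to vary like the other tissues. Without the 3-day seed the median change per gene was 0.653 in body CHG, 0.175 in body CG and 0.244 in body CHH, against 0.739, 0.331 and 0.301 with both seeds. The median SE was 1.91, 3.79 and 0.583, against 1.46, 2.88 and 0.458, so smaller changes and larger SEs came together. The correlation of mean upstream CHH with day ran from 0.771 without the 25-day to 0.923 without the 11-day library and missed the threshold without the 9-, 13-, 15-, 20- or 25-day library. For CHG it ran from -0.912 to -0.559 in the body and from -0.869 to -0.479 upstream, and it passed only without the 11-day library. The median over genes in place of the mean gave 0.645 for upstream CHH, which missed the threshold (exact permutation, adjusted p = 0.149). All 8 of 126 list calls ended with an estimated correlation: 0.388 and 0.281 for storage proteins and 0.355 and 0.281 for the transfer layer (seed, body CG and CHG), 0.644 and 0.881 for the transfer layer (leaf, upstream CG and CHG), 0.428 for methylation machinery (trend, upstream CHG) and 0.449 for starch synthesis (trend, upstream CHH). Of 854 values of named genes under alternatives, 259 no longer passed, 5 newly passed and 0 reversed. Of the genes past the threshold in the fit for the lone leaf, ftr1 (body CG), fl2 (body CHG), esr1 (body CHG) and esr3 (upstream CHG) passed in all of their 17, 17, 16 and 17 alternatives, while pbf1 (body CG) passed in 7 of 17, esr2 in 8 of 17 and lox3 in 9 of 16. In the CHH trend nfd102 and pdi7 passed in 5 of 18 alternatives, COAC2 in 6, met2 in 7, nrp1 in 9, act1 in 10 and z1A1_2 in 11. The genes named for seed passed in 7 to 11 of 12 or 13. Coverage minimums of 5 and 20 moved no count by over 1.5 times. Depth limits single genes with few calls most, such as esr1 with as few as 10 calls in a library. For whole seed, endosperm libraries other than the 10-day one were not left out in turn.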

Other observations

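The tests of gene classes were chosen after the data were seen. In the 9290 genes with a body CHG level of at least 20% in leaf, the mean CHG level was 62.4% in whole seed (n = 2) and 52.0% ± 3.20 (SD, n = 8) in endosperm, a difference of 10.4 percentage points (exact permutation p = 0.022, the smallest the splits can give, adjusted over 18 comparisons p = 0.050), which did not pass the threshold after adjustment. The CHG difference was 0.207 percentage points (exact permutation p = 0.267, adjusted p = 0.300) in the 3305 genes with at least 20% CG and under 5% CHG in leaf, and 0.165 (exact permutation p = 0.422, adjusted p = 0.447) in the 10862 genes under 5% in both. In the class of 3305 genes the mean CG level was 34.2% and 31.1% (exact permutation p = 0.022, adjusted p = 0.050). Across the endosperm stages the CHG level of the first class was 57.1% at day 7 and 49.7% at day 25 (r = -0.589, exact permutation p = 0.127, adjusted p = 0.289; rho = -0.714, exact permutation p = 0.0576, adjusted p = 0.156; r = -0.448 without days 20 and 25).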
